A study of Mus musculus with 17 samples.

How the data were processed

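RNA from the hypothalamus of 17 male C57BL/6J mice was sequenced, 1 library per mouse. Per the labels, the mice were bought at 8 weeks of age, housed singly and given a baseline period of 30 days, then kept for 3 months on 1 of 3 feeding regimens. The control group had free access to the standard diet. The calorie dilution group (CD) had free access to a diet diluted with cellulose. The calorie restriction group (CR) received standard diet in the amount that matched the energy absorbed by CD mice, given shortly before the dark phase. The labels pair CR mice with CD mice for this feeding but do not state which mouse with which, so the comparison of CR with CD was fitted unpaired. The labels state no library batch, no time of death and no strandedness.

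The deposited table holds CPM values (read counts scaled to a common library size) for 16257 gene symbols in 17 columns, scaled by the authors with a factor per library. Per the labels, the authors' tools were FastQC, HISAT2 2.1.0, featureCounts 1.5.1 and edgeR, with the genome build GRCm38; the role of each tool, the gene annotation and any filter are not stated. In every column the values were whole multiples of 1 step, and 100% of the values above 0 lay within 0.01 reads of a whole number of reads, the largest distance being 0.00213 reads. The recovered totals per library ran from 15891824 to 17047261 reads, and 1 read equalled 0.0581 to 0.0617 CPM. The column totals were 0.972 to 1.010 times the total of plain CPM, so a scaling factor beyond the total had been applied. Another 9 columns of the table had no name and no value. In 24 gene names a spreadsheet date had replaced the symbol, and 1 name appeared more than once; these genes were kept in the fits and none is named.

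The 3 comparisons were CR against control, CD against control and CR against CD. CPM values were kept as scaled in the table, 0.25 CPM was added and log2 was taken. This pseudocount equals 4.05 to 4.31 reads. Genes with a mean of at least 0.5 CPM over the 17 libraries were tested, which left 16229. All 17 libraries entered 1 limma fit (limma 3.58.1 in R 4.3.3, empirical Bayes with a trend, robust) with a mean per group and no block or covariate. P values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison. A gene is called when its adjusted p is under 0.05, and adjusted p values of genes are from limma unless another tool is named. The test, the filter, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined.

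The genes named are, in each comparison, the 10 with the highest and the 10 with the lowest log2 fold change among called genes with a mean of at least 2 CPM and a symbol that is not a predicted gene or clone. To these were added 10 core feeding genes whatever their p, and up to 4 members of each described list with the smallest p. Of the genes this rule names, 1 is not reported here. Gene coordinates were taken from GENCODE M21 on GRCm38 by symbol, which matched 15411 symbols (95.0%). Of 46 named genes, 11 share exonic bases with another annotated gene, so some of their reads could not be assigned with certainty when the strand is unknown.

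Of 55 gene lists fixed beforehand, 54 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. The lists hold 904 genes, of which 870 were measured. Camera with an estimated correlation and fry were run as alternatives. An exact permutation test of each list's mean per library, over all regroupings of the libraries of both groups, was added after seeing the data. Intervals at the 95% level for list means are from a linear model with a mean per group. The lists described are immediate early genes, heat shock, glucocorticoid-induced genes, oligodendrocyte markers, cytosolic ribosomal proteins, the nuclear-encoded respiratory chain, orexigenic and anorexigenic peptides and receptors, and leptin and JAK-STAT signalling. Microglia markers are given beside those of oligodendrocytes. For cold-inducible RNA-binding genes and for insulin, FOXO and mTOR signalling only the exact permutation test is given. Further lists were called and are not described.

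The overlap of calls against the shared control group was compared with the product of the call rates, with 50 simulations of unchanged groups set against the same control libraries, and with 20 splits of the control libraries into sets of 3. Unchanged groups give almost no calls whatever controls they share, so the simulations bear on the correlation of fold changes and not on the number of shared calls. In them all libraries, control libraries included, were drawn anew and each gene independently, without the correlation between genes of real libraries. The fit was also tested on simulated data, in which 200 genes per comparison were changed and drawn with the dispersion of these libraries. At a log2 change of 0.5, 71% of the changed genes were recovered for CR against control, 75% for CD against control and 71% for CR against CD. At a log2 change of 1 the shares were 88%, 91% and 88%. A list of 76 ribosomal protein genes was shifted by -0.2 as well. Camera found it in each comparison, with 1 list called of 54, and 14, 15 and 10 of its genes were called. The simulated genes were drawn independently of each other. The run therefore does not show how often camera calls unchanged lists when genes are correlated, as in real libraries. False calls, of genes neither changed nor shifted, numbered 12 of 185, 9 of 190 and 12 of 181 calls.

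Alternatives changed the pseudocount, the filter, the scaling, the threshold, array weights, the groups in the fit, a block by replicate number, and covariates for oligodendrocyte markers or for markers of neighbouring brain regions. Counts of recovered reads were tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. Each of the 17 libraries was left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Food intake, body composition and behaviour were not analysed here.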

Results

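Gene expression was measured by RNA sequencing in the hypothalamus of 6 control mice, 5 mice under calorie restriction (CR) and 6 mice under calorie dilution (CD). The libraries held 15891824 to 16888770 assigned reads in the control group, 16714278 to 17047261 in CR and 16783866 to 17014837 in CD. Mitochondrially encoded transcripts took 8.35% ± 0.491 (SD, n = 6) of the reads in control, 8.37% ± 0.566 (SD, n = 5) in CR and 8.38% ± 0.188 (SD, n = 6) in CD. Values are normalised read counts in CPM, and fold changes are differences of group means on the log2 scale.

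The comparison of CR with control asks how hypothalamic expression differed under a lower intake of the standard diet, given shortly before the dark phase. Control mice fed freely, so the amount and the timing of food cannot be told apart here. Of 16229 genes tested, 485 were called, 185 higher and 300 lower in CR, and 2843 had an unadjusted p under 0.05. The median absolute log2 fold change of the called genes was 0.30. An absolute log2 fold change above 1 was reached by 5 of the higher and 11 of the lower genes. The count fell to 321 without control replicate 1, to 309 without CR replicate 2, to 309 without CR replicate 3, to 318 without CR replicate 4 and to 202 without CR replicate 6. With the mean of the oligodendrocyte markers as a covariate it was 23. In that fit all 485 genes kept their sign; their median absolute log2 fold change was 0.27 in place of 0.30 and their median standard error 0.093 in place of 0.067.

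The genes with the largest decreases in CR were Hspa1b, Fos, Fosb, Rrad, Fosl2, Hspa1a, Nr4a3, Egr1, Gem and Pomc. Fos (chromosome 12, 85473890 to 85477273) had 61.3 ± 15.1 CPM (SD, n = 6) in control and 13.7 ± 4.47 CPM (SD, n = 5) in CR, a log2 fold change of -2.16 (SE 0.23, adjusted p = 0.000298). Fosb (chromosome 7, 19302696 to 19310051) fell by 2.04 on the log2 scale (adjusted p = 9.93e-06) and Fosl2 (chromosome 5, 32135801 to 32157842) fell by 1.45 (adjusted p = 2.66e-06). Hspa1b (chromosome 17, 34956436 to 34959238) went from 6.88 ± 3.87 CPM (SD, n = 6) to 1.15 ± 0.204 CPM (SD, n = 5), a log2 fold change of -2.21 (SE 0.25, adjusted p = 5.09e-05). Hspa1b and Hspa1a are near-identical paralogs whose reads cannot always be assigned to 1 of them, and Hspa1a also shares 19.0% of its exonic bases with a gene on the opposite strand. Rrad, a small GTPase gene on chromosome 8 (104628070 to 104631327), fell by 1.69 (adjusted p = 3.01e-07). In these 6 genes, and in Nr4a3 and Gem, all 5 CR values lay below all 6 control values, while Egr1 and Pomc overlapped. Egr1 fell by 1.11 (adjusted p = 0.0478). Its call was lost in 14 of the 17 fits that left out 1 library, with adjusted p from 0.0510 to 0.111; it was kept without control replicate 3, CR replicate 3 or CD replicate 1.

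Among the genes with the largest increases in CR were Plin4, Sult1a1, Hif3a, Pla2g3, Slc25a34, Fbln5, Hr, Phyhd1 and Col5a3, with log2 fold changes from 2.097 down to 0.79. Plin4 (perilipin 4, chromosome 17, 56100591 to 56109803) had 9.11 ± 3.33 CPM (SD, n = 6) in control and 40.7 ± 19.2 CPM (SD, n = 5) in CR, a log2 fold change of 2.097 (SE 0.33, adjusted p = 0.00387). In 8 of these 9 genes all 5 CR values lay above all 6 control values; the exception was Hif3a. Phyhd1 shares 47.0% of its exonic bases with another gene on the same strand. With the oligodendrocyte covariate limma called none of these 9 genes; their log2 fold changes were 0.73 to 1.96 in place of 0.79 to 2.097, with standard errors of 0.21 to 0.49 in place of 0.14 to 0.33, so the calls ended mostly through wider standard errors. Without CR replicate 6 the calls of Sult1a1 (adjusted p = 0.0510) and Phyhd1 (adjusted p = 0.0629) were lost. Hif3a lost its call without control replicate 1, control replicate 4, control replicate 6, CR replicate 1, CR replicate 3, CR replicate 4 or CR replicate 6, with adjusted p from 0.0563 to 0.0827.

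Among the 10 core feeding genes, Npy (chromosome 6, 49822710 to 49829507) had 15.8 ± 3.32 CPM (SD, n = 6) in control, 25.4 ± 5.23 CPM (SD, n = 5) in CR and 24.9 ± 4.70 CPM (SD, n = 6) in CD. Its log2 fold change against control was 0.68 in CR (SE 0.16, adjusted p = 0.0354) and 0.66 in CD (SE 0.16, adjusted p = 0.0292). Pomc (chromosome 12, 3954951 to 3960642) had 9.26 ± 2.66 CPM (SD, n = 6) in control, 5.05 ± 1.70 CPM (SD, n = 5) in CR and 4.66 ± 0.965 CPM (SD, n = 6) in CD. It fell by 0.85 in CR (SE 0.21, adjusted p = 0.0367) and by 0.93 in CD (SE 0.20, adjusted p = 0.0169). Agrp (chromosome 8, 105566698 to 105637393) had 1.52 ± 0.560 CPM (SD, n = 6) in control, 2.40 ± 0.673 CPM (SD, n = 5) in CR and 2.60 ± 0.319 CPM (SD, n = 6) in CD, and 11.3% of its exonic bases overlap another gene. Its log2 fold change was 0.75 in CD (SE 0.20, adjusted p = 0.0382) and 0.61 in CR (SE 0.21, adjusted p = 0.112), where it was not called. The CD values of Npy all lay above the control values; the other comparisons of these 3 genes with control overlapped. Cartpt, Hcrt, Pmch, Ghsr, Lepr, Socs3 and Mc4r were not called in any comparison. The smallest adjusted p among these 7 genes was 0.0852, for Mc4r in CD against control, and Mc4r was called without control replicate 1 (adjusted p = 0.0399). No core gene was called between CR and CD, where log2 differences were 0.022 for Npy, 0.079 for Pomc and -0.13 for Agrp.

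Several of these calls lay near the threshold and were lost when any 1 of several libraries was left out. Npy lost its call in CR without control replicate 1, 2, 4 or 6 or CR replicate 2, 3 or 6, with adjusted p from 0.0594 to 0.0940. In CD Npy lost it without control replicate 1, 2, 4 or 6 or CD replicate 1, 2 or 3 (0.0531 to 0.0626). Pomc lost its call in CR without control replicate 4, 5 or 6 or CR replicate 1, 2, 3 or 4 (0.0683 to 0.0870), and kept it in CD in all 17 fits that left out 1 library. Agrp lost its call in CD without control replicate 1, 2 or 3 or CD replicate 2, 3, 4 or 6 (0.0603 to 0.0957). With the oligodendrocyte covariate Npy and Pomc in CR and Agrp in CD were not called, while Npy and Pomc in CD were. In that fit the log2 fold change in CR was 0.31 for Npy (SE 0.20) and -1.26 for Pomc (SE 0.27), and that of Agrp in CD was 0.67 (SE 0.20). Pmch shares 58.1% of its exonic bases with a gene on the opposite strand.

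**Figure D1:**
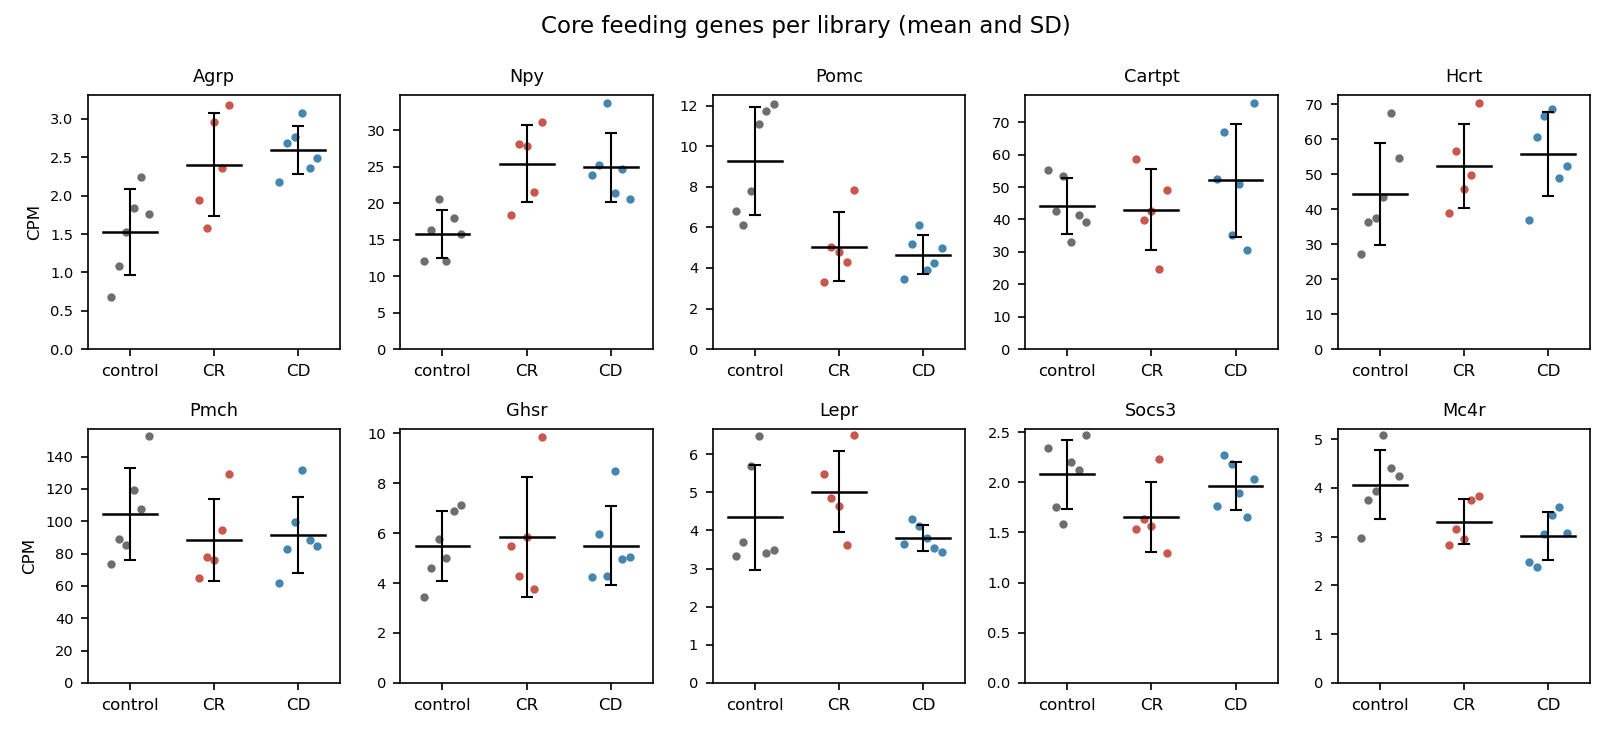
Normalised read counts (CPM, vertical axis, from 0) of the 10 core feeding genes in control (n = 6), CR (n = 5) and CD (n = 6); points are libraries, horizontal lines group means and bars the SD. Mean Npy was 15.8 CPM in control, 25.4 CPM in CR and 24.9 CPM in CD.

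The comparison of CD with control asks what feeding freely on the diluted diet did. Of the genes tested, 585 were called, 187 higher and 398 lower in CD, and 2939 had an unadjusted p under 0.05. Their median absolute log2 fold change was 0.30. The count fell to 306 without control replicate 2, to 354 without control replicate 3, to 351 without control replicate 6, to 368 without CD replicate 2, to 329 without CD replicate 3 and to 309 without CD replicate 6. With the oligodendrocyte covariate it was 504.

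The genes with the largest decreases in CD were Fos, Fosb, Hspa1b, Fosl2, Nr4a3, Rrad, Egr1, Hspa1a, Junb and Sgk1. Fos had 10.3 ± 2.11 CPM (SD, n = 6) in CD, a log2 fold change of -2.53 (SE 0.22, adjusted p = 1.83e-05). Fosl2 fell by 1.81 on the log2 scale (adjusted p = 4.37e-08) and Egr1 (chromosome 18, 34859823 to 34864984) by 1.52 (adjusted p = 0.00719). In 9 of these 10 genes all 6 CD values lay below all 6 control values; the exception was Junb, which fell by 1.14 (adjusted p = 0.0255) and lost its call without control replicate 1, control replicate 2, CD replicate 2 or CD replicate 6 (adjusted p from 0.0510 to 0.0616). Sgk1 (chromosome 10, 21882184 to 21999903) had 204 ± 44.4 CPM (SD, n = 6) in control and 95.1 ± 17.2 CPM (SD, n = 6) in CD, a log2 fold change of -1.09 (SE 0.19, adjusted p = 0.00718); in CR it had 190 ± 46.3 CPM (SD, n = 5).

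The genes with the largest increases in CD were Cldn5, Hist1h1c, Sox18, Trpv4, Slc25a34, Agrp, Col5a3, Fbln5, Npy and Drd5, with log2 fold changes from 0.88 down to 0.65. Cldn5 (claudin 5, chromosome 16, 18776847 to 18778262) had 6.60 ± 1.51 CPM (SD, n = 6) in control and 12.2 ± 1.76 CPM (SD, n = 6) in CD, a log2 fold change of 0.88 (SE 0.12, adjusted p = 0.000306). For Cldn5, Slc25a34, Col5a3, Fbln5 and Npy all 6 CD values lay above all 6 control values. Drd5 shares 48.6% of its exonic bases with an antisense gene. Hist1h1c (adjusted p = 0.0345) lost its call without control replicate 1, 2, 3 or 6 or CD replicate 1, 2 or 6, with adjusted p from 0.0603 to 0.0782. Trpv4 (adjusted p = 0.0279) lost its call without control replicate 2, 3 or 6 or CD replicate 1, 3 or 6, with adjusted p from 0.0542 to 0.0765.

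**Figure D2:**
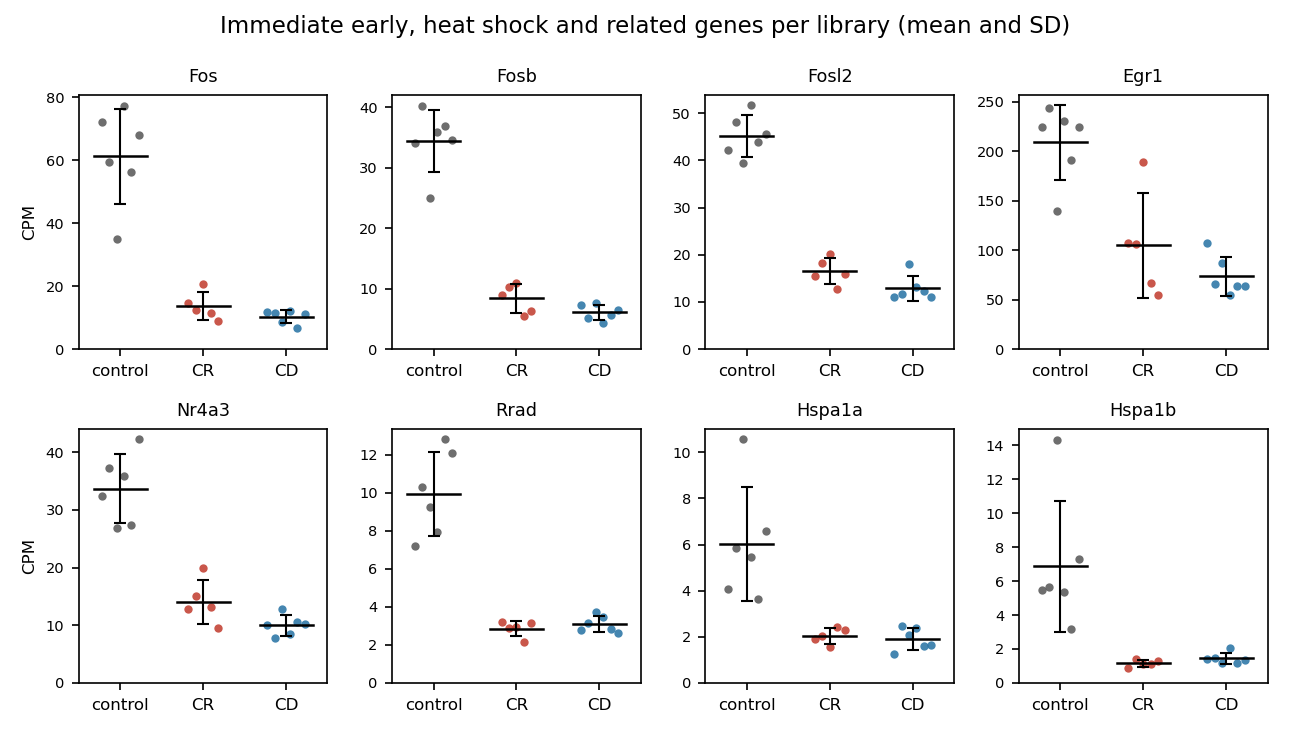
Normalised read counts (CPM, vertical axis, from 0) of 8 immediate early, heat shock and related genes in control (n = 6), CR (n = 5) and CD (n = 6); points are libraries, horizontal lines group means and bars the SD. Mean Fos was 61.3 CPM in control, 13.7 CPM in CR and 10.3 CPM in CD.

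In all, 202 genes were called against control in both CR and CD, 66 higher and 136 lower in both, and 0 in opposite directions. Independent calls at these rates would share 2.13 higher and 7.36 lower genes. Both comparisons use the same control libraries, which adds to the overlap. With the control libraries split into sets of 3, a different set for each diet, a mean of 13.6 genes was shared (range 7 to 20 over 20 splits), against 28.1 when both diets were compared with the same set. These fits hold fewer control libraries, so their counts can be set against each other but not against the 202 or the independent rates above. Across genes, which are not independent replicates, the correlation of the fold changes was 0.688, against a mean of 0.471 in 50 simulations of unchanged groups with shared controls. The simulations drew each gene independently, so they give no spread against which the excess over 0.471 can be judged. In the real libraries the correlation was 0.328 on average (range 0.158 to 0.505) with a different set of 3 control libraries for each diet and 0.755 with the same set. Of the 283 genes called in CR alone 4 differed between CR and CD, and of the 383 called in CD alone 8 differed. Of the 202 shared genes 0 differed between CR and CD. Genes chosen for calls of the same sign against shared controls are unlikely to differ there, so this 0 is no evidence of equal effects. In the comparison of CR with CD limma called 12 genes, edgeR 15 and DESeq2 73, and 1548 had an unadjusted p under 0.05 in limma. The shared count fell to 121 without control replicate 2, to 129 without control replicate 6, to 133 without CR replicate 2 and to 110 without CR replicate 6.

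**Figure D3:**
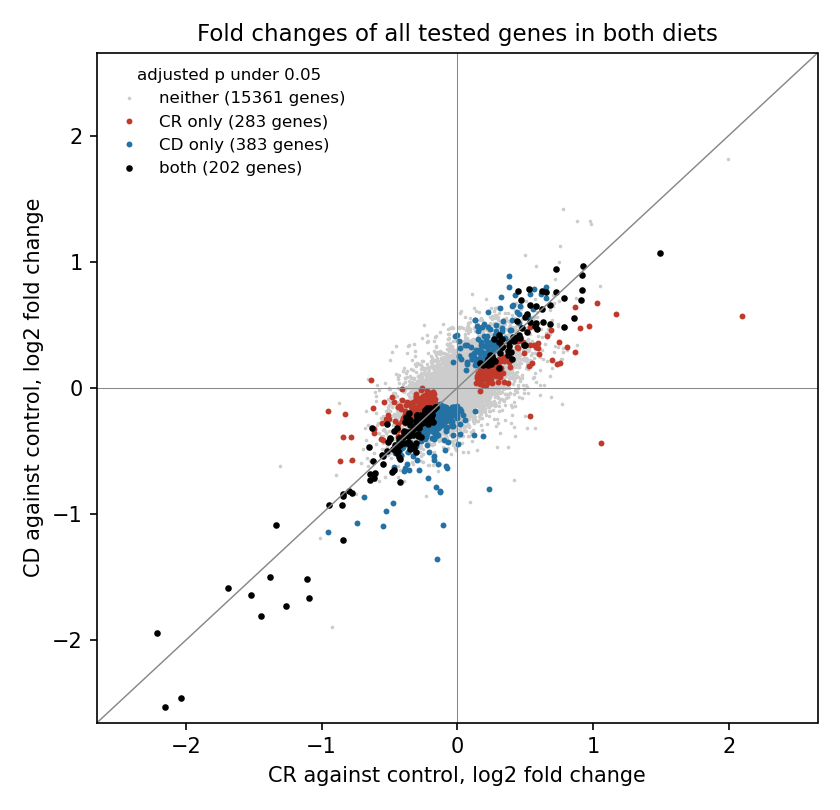
Log2 fold change against control in CR (horizontal axis) and in CD (vertical axis) for each of the 16229 genes tested; colours mark genes called in CR only (283), CD only (383) or both (202), and the diagonal marks equal change. The genes called in both lie in the quadrants of the same sign.

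The comparison of CR with CD asks whether the regimens differed at a matched absorbed energy intake. It called 12 genes, 11 higher and 1 lower in CR: Hif3a, Fmo2, Net1, Plekhf1, Txnip, Nfkbia, Aff1, Per1, Elmsan1 and Fam214a, a clone that the naming rule leaves out, and Insc, which was lower. Per1 (chromosome 11, 69095217 to 69109960) had 179 ± 19.1 CPM (SD, n = 5) in CR and 130 ± 11.7 CPM (SD, n = 6) in CD, a log2 difference of 0.46 (SE 0.067, adjusted p = 0.00838), with 198 ± 10.6 CPM (SD, n = 6) in control. Hif3a (chromosome 7, 17031507 to 17062427) had 42.5 ± 8.46 CPM (SD, n = 5) in CR and 14.99 ± 3.62 CPM (SD, n = 6) in CD, a log2 difference of 1.498 (SE 0.24, adjusted p = 0.0349), with 20.9 ± 6.96 CPM (SD, n = 6) in control. Insc (chromosome 7, 114743694 to 114850383) had 3.36 ± 0.558 CPM (SD, n = 5) in CR and 5.55 ± 0.559 CPM (SD, n = 6) in CD, a log2 difference of -0.69 (SE 0.11, adjusted p = 0.0128). In 9 of the 11 named genes the CR and CD values did not overlap; the exceptions were Fmo2 and Net1. Txnip shares 19.4% of its exonic bases with an antisense gene.

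The number of genes called between CR and CD changed with single libraries. It was 7 without control replicate 3, 6 without CR replicate 1, 33 without CR replicate 2, 1 without CR replicate 3, 5 without CR replicate 4 and 3 without CR replicate 6. It was 7 without CD replicate 2, 6 without CD replicate 3, 6 without CD replicate 4 and 7 without CD replicate 6. With the oligodendrocyte covariate limma called 0 genes, with 1083 at an unadjusted p under 0.05; the 12 genes kept their sign, and their median absolute log2 difference was 0.59 in place of 0.63, with a median standard error of 0.14 in place of 0.11. Without a covariate edgeR called 15 genes and DESeq2 73. Per1 was called in every fit that left out 1 library. Elmsan1 lost its call without CR replicate 3 (adjusted p = 0.0573), Txnip without CR replicate 3 or 6 (0.0627 to 0.0726), Insc without CR replicate 3, 4 or 6 (0.0572 to 0.0726) and Aff1 without CR replicate 1, 3, 4 or 6 (0.0581 to 0.0770). Plekhf1 lost its call without control replicate 3, CR replicate 1, 3 or 6 or CD replicate 3, 4 or 5 (0.0510 to 0.159). Fmo2 lost its call without CR replicate 1, 3, 4 or 6 or CD replicate 2, 3, 4 or 6 (0.0711 to 0.159). Hif3a lost its call without control replicate 2, 3 or 6, CR replicate 1, 3, 4 or 6 or CD replicate 1, 2, 3, 4 or 6 (0.0504 to 0.159). Net1 lost its call without control replicate 1, 2, 3 or 6, CR replicate 3, 4 or 6 or CD replicate 2, 3, 4, 5 or 6 (0.0504 to 0.159). Nfkbia lost its call without control replicate 1, 2, 3 or 6, CR replicate 1, 3, 4 or 6 or CD replicate 2, 3, 4, 5 or 6 (0.0504 to 0.159). Fam214a lost its call without control replicate 1, 2 or 3, CR replicate 1, 3, 4 or 6 or CD replicate 2, 3, 4 or 6 (0.0537 to 0.249).

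Of 54 gene lists, camera with a preset correlation called 16 in CR against control, 11 in CD against control and 10 in CR against CD. With the correlation estimated from the data 0 of these calls held in any comparison, and fry called 7, 4 and 2. The exact permutation test of the list means, added after seeing the data, called 0. Its smallest possible p was 0.00216, which for 1 list alone gives an adjusted p of 0.117, so it had little room to call any. The number of lists called in CD against control was 17 without control replicate 1, and that in CR against CD was 16 without CD replicate 1. Regrouping the libraries of both groups at random gave as many lists in 47, 61 and 64 of 100 regroupings, the real one included. For lists, the adjusted p values that follow are from camera with the preset correlation unless stated otherwise.

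Immediate early genes were lower in CR than in control, with a positive log2 fold change in 2 of 24 members and a median of -0.58 (adjusted p = 1.07e-14; 0.239 with the estimated correlation; exact permutation p = 0.00433, adjusted 0.0779). Over all genes 7 of the members were called lower, and 14 when adjusted over the list alone. In CD the median was -0.66, 3 of 24 members were positive (adjusted p = 1.84e-17; 0.161 with the estimated correlation; exact permutation p = 0.00216, adjusted 0.0584), 11 were called lower over all genes and 16 adjusted over the list alone. Heat shock genes had 0 positive members of 19 in either diet. Their median was -0.22 in CR (adjusted p = 1.07e-14; 0.196 with the estimated correlation) and -0.19 in CD (adjusted p = 2.58e-12; 0.161 with the estimated correlation). The exact permutation p was 0.00216 in both, the smallest the regroupings can give (adjusted 0.0584). In each diet 7 heat shock genes were called lower over all genes; adjusted over the list alone, 13 were lower in CR and 11 in CD. Dnajb1 fell by 0.80 in CR (adjusted p = 4.88e-08) and by 0.82 in CD (adjusted p = 1.14e-08). Cryab fell by 0.52 in CR (adjusted p = 0.000918) and Dnaja1 by 0.20 in CD (adjusted p = 0.00761).

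All 20 glucocorticoid-induced genes had higher fitted values in CR than in CD, with a median log2 difference of 0.55 (adjusted p = 9.46e-25; 0.108 with the estimated correlation; exact permutation p = 0.00216, the smallest possible, adjusted 0.117). Over all genes 3 were called, Per1, Hif3a and Nfkbia, and 17 adjusted over the list alone. Errfi1 followed with a log2 difference of 0.41 (adjusted p = 0.135). Against control the median was 0.28 in CR (13 of 20 positive, adjusted p = 0.000469; 0.733 with the estimated correlation; exact permutation p = 0.0498, adjusted 0.316) and -0.35 in CD (6 of 20 positive, adjusted p = 0.00125; 0.729 with the estimated correlation; exact permutation p = 0.0693, adjusted 0.351). In CR 4 members were called higher over all genes, Plin4, Pla2g3, Sult1a1 and Hif3a, and 7 adjusted over the list alone. In CD 7 were called lower over all genes and 7 adjusted over the list alone, where 4 were also higher; Per1 fell by 0.61 (adjusted p = 7.79e-06), Ddit4 by 0.57 (adjusted p = 0.000758), Nfkbia by 0.63 (adjusted p = 0.00128) and Tsc22d3 by 0.71 (adjusted p = 0.00192).

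Oligodendrocyte markers were lower in CR than in control, with a median of -0.20 and 1 of 14 members positive (adjusted p = 4.99e-08; 0.360 with the estimated correlation; exact permutation p = 0.00866, adjusted 0.0779). Over all genes 5 were called lower, and 8 adjusted over the list alone, with Ugt8a at -0.51 (adjusted p = 0.00358) and Ermn at -0.32 (adjusted p = 0.00472). They were also lower in CR than in CD, with a median of -0.19 and 0 of 14 members positive (adjusted p = 7.48e-08; 0.499 with the estimated correlation; exact permutation p = 0.00649, adjusted 0.117); over all genes 0 were called by limma, and 8 were lower adjusted over the list alone. In CD against control the list was not called (median -0.059, adjusted p = 0.206). Microglia markers were also lower in CR than in control, with a median of -0.16 and 1 of 16 members positive (adjusted p = 0.000107; 0.360 with the estimated correlation; exact permutation p = 0.00649, adjusted 0.0779), and in CD, with a median of -0.092 and 3 of 16 positive (adjusted p = 0.0334; 0.729 with the estimated correlation; exact permutation p = 0.0346, adjusted 0.267). In CD the list was not called without control replicate 3, 4 or 5 or CD replicate 4 or 5 (adjusted p from 0.0576 to 0.117).

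Cytosolic ribosomal protein genes were lower in CR than in CD by a median of -0.12, with 4 of 76 positive (adjusted p = 1.04e-14; exact permutation p = 0.0130, adjusted 0.175). Genes of the nuclear-encoded respiratory chain were lower by a median of -0.10, with 1 of 72 positive (adjusted p = 1.04e-14; exact permutation p = 0.0195, adjusted 0.210). With the estimated correlation the adjusted p was 0.499 for both. Against control in CR the medians were -0.089 (adjusted p = 2.05e-05; 0.733 with the estimated correlation; exact permutation p = 0.210, adjusted 0.539) and -0.074 (adjusted p = 8.66e-05; 0.733 with the estimated correlation; exact permutation p = 0.221, adjusted 0.539), and without control replicate 5 neither was called (adjusted p = 0.0712 and 0.0842). Neither list was called in CD against control (adjusted p = 0.162 and 0.0956). Orexigenic peptides and receptors were not called in any comparison (adjusted p = 0.410 in CR against control, 0.594 in CD against control and 0.742 in CR against CD). The same held for anorexigenic peptides and receptors (0.827, 0.542 and 0.561) and for leptin and JAK-STAT signalling (0.156, 0.0990 and 0.752). Relative to the mean of all genes, cold-inducible RNA-binding and related genes differed by -0.15 in CR against control (exact permutation p = 0.00216, adjusted 0.0584). In CD against control they differed by -0.14 (exact permutation p = 0.00866, adjusted 0.117). Insulin, FOXO and mTOR signalling differed by 0.12 in CR against CD (exact permutation p = 0.00433, adjusted 0.117). In CD against control it differed by -0.088 (exact permutation p = 0.00649, adjusted 0.117).

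**Figure D4:**
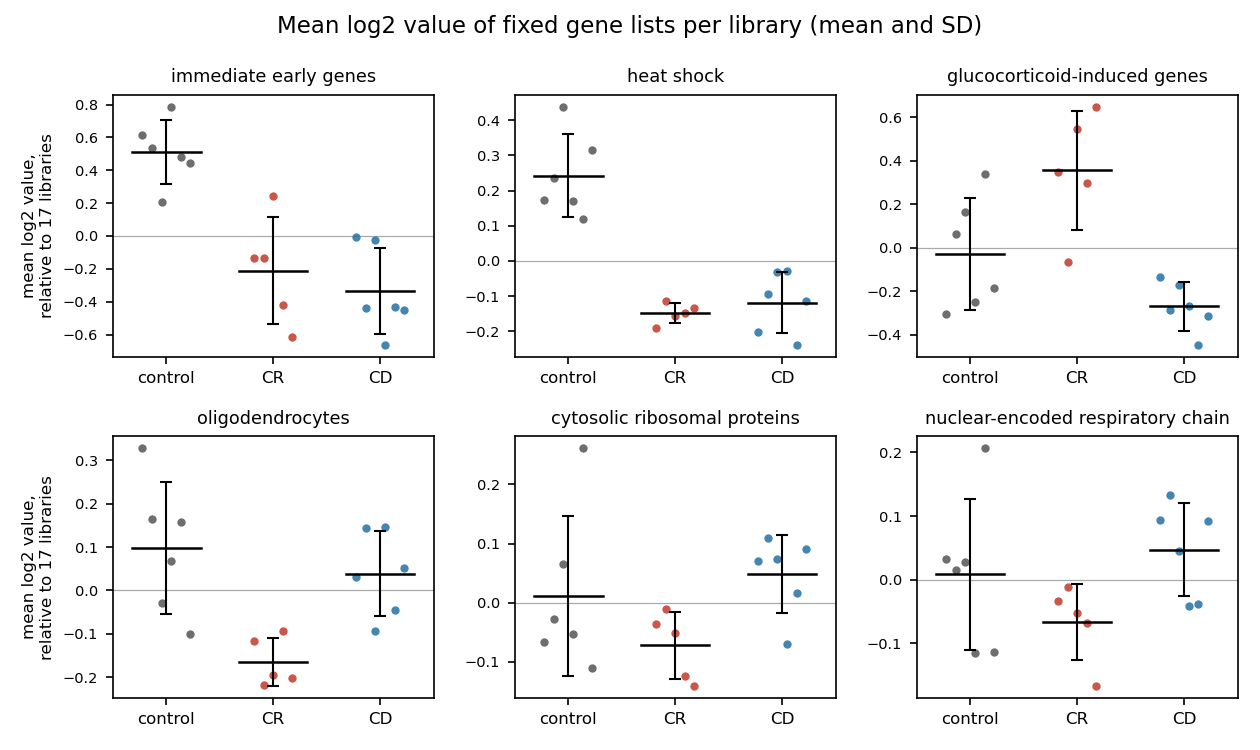
Mean log2 value of the members of 6 gene lists per library (vertical axis, relative to the mean of all 17 libraries) in control (n = 6), CR (n = 5) and CD (n = 6); points are libraries, horizontal lines group means and bars the SD. The glucocorticoid-induced genes averaged 0.36 in CR, -0.27 in CD and -0.028 in control.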

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

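The tests of the clock score, of the handling of the control mice, of the weight of single libraries and of whether 0 lies within an interval after a covariate or a trend removal were chosen after related values had been seen, as was the exact permutation test of list means.

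Within a group, the highest or lowest library was tested for its distance from the others (Dixon's test at the 95% level) in 138 combinations of a named gene and a group and in 69 of a list called in any comparison and a group, on the log2 scale. Of these, 11 combinations with a gene and 3 with a list had such a library. Chance alone gives about 1 in 20, or 6.90 and 3.45. In CD replicate 5, Sult1a1 was at 7.56 CPM (12.3 to 13.6 in the other CD libraries) and Hr at 40.5 CPM (58.1 to 68.4). In CR replicate 6, Fbln5 was at 42.9 CPM (21.9 to 25.3 in the other CR libraries) and Hr at 144.7 CPM (70.0 to 82.6). Slc25a34 was low in control replicate 6, at 4.18 CPM, and Fosb in control replicate 3, at 24.9 CPM. Rrad was low in CR replicate 4, at 2.18 CPM, and Fosl2 was high in CD replicate 3, at 18.1 CPM. Aff1 was low in CR replicate 2, at 29.0 CPM, and in CD replicate 6, at 21.0 CPM. Per1 was low in CD replicate 4, at 108 CPM. Relative to the mean of all 17 libraries on the log2 scale, the circadian clock list was low in control replicate 4, at -0.12. The list of insulin, FOXO and mTOR signalling was high in control replicate 3, at 0.17, and low in CR replicate 4, at -0.035. No explanation of these values was tested.

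Other divisions of the same libraries into groups of the same sizes were fitted, 100 of the 462 possible for each comparison, the real one included. For CR against control 1 of the 100 called as many genes, the real one with 485, and the highest other called 95, so chance can be excluded for that count. For CD against control 1 of the 100 called as many, the real one with 585, so chance can be excluded. The highest other called 504 genes; it exchanged CD replicate 5 and control replicate 5, and 139 of its genes were among the real calls. For CR against CD 2 of the 100 called as many as the real 12, a share under an unadjusted 5%. The count is small and only 100 of the 462 divisions were fitted, so chance is not firmly excluded. The other of these 2 divisions put CR replicates 1, 2 and 3 and CD replicates 1 and 5 in 1 group. It called 47 genes, several times the real count, and 0 of them were among the real calls. A count of that size points to differences among these libraries that do not follow diet. It rests on 1 division, and the source of the differences was not tested. The list of striatum and basal forebrain markers was at 0.28 to 1.16 in the libraries of this group. In the other CR and CD libraries it was at -1.09 to -0.25, except CD replicate 3 at 0.86. This list was picked after the division was seen. GABA neuron markers divided these libraries likewise, at 0.11 to 0.27 against -0.23 to -0.11, again except CD replicate 3 (0.14). So did the clock score described below, at -0.34 to -0.056 against 0.026 to 0.23, except CD replicate 3 (-0.49). These values therefore do not single out 1 tissue or source. For the number of lists called by camera chance cannot be excluded in any comparison. As many lists were called in 47 of 100 divisions for CR against control (real 16, highest other 30), in 61 for CD against control (real 11, highest other 26) and in 64 for CR against CD (real 10, highest other 28).

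The first pattern weighed is the lower level of immediate early and heat shock genes in both diets. The mean log2 difference over the members of both lists, averaged over CR and CD against control, was -0.60 (95% interval -0.75 to -0.45). Tissue that varies along the first principal component of thalamus, striatum and cortex markers is argued against as the whole cause. With this component as a covariate the difference was -0.63 (95% interval -0.75 to -0.50, which leaves out 0), 104% of its value. Midbrain and mammillary markers were not part of it, so outside tissue in general stays open. A different time of day at sampling cannot be told apart from diet. The clock score, the mean of 7 clock genes minus that of 3 genes of the opposite phase, differed by -0.16 (95% interval -0.37 to 0.055, permutation p = 0.116). The interval is too wide to exclude a shift. In every library but control replicate 3 the score and the list of striatum and basal forebrain markers had opposite signs. The score was -0.49 in CD replicate 3 (list at 0.86) and 0.23 in CD replicate 4 (list at -1.09). It may thus follow the dissection and does not isolate the time of day. Handling or killing order cannot be told apart from diet either. All 6 control libraries lay above all diet libraries, and the labels give neither order nor time of death. Both gene classes respond within a short time to arousal and stress, so a difference in the last hour might produce this pattern as well as 3 months of diet. An effect of the diets also stays open.

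The second pattern is the higher level of glucocorticoid-induced genes in CR than in CD, a mean log2 difference of 0.62 (95% interval 0.34 to 0.91). A single library is argued against as its source, since with 1 library left out the lowest difference was 0.55, 88.3% of its value. Leaving out several libraries together was not tested. CR replicate 2, at -0.065, lay lowest among the CR libraries. The share of oligodendrocytes is argued against as the whole cause: with their markers as a covariate the difference was 0.60 (95.8% of its value), and its 95% interval, 0.21 to 0.99, leaves out 0. A part played by it stays open, since this interval reaches below 50% of the difference. A different time of day stays open as well. The clock score differed by 0.072 between CR and CD (95% interval -0.18 to 0.33, exact permutation p = 0.619), which leaves room for a shift of 0.3. Its relation to the striatum markers, given above, limits this test as well. Glucocorticoid secretion follows the time of feeding, and CR mice had their food at a set time while CD mice ate freely. The timing of the meal, the regimens themselves or the stress of restriction may each underlie the difference, and these data do not separate them. Per1 belongs to the clock as well as to this list.

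The third pattern is the lower level of cytosolic ribosomal protein and respiratory chain genes in CR than in CD, a mean log2 difference of -0.12 (95% interval -0.23 to -0.00113). After a trend on transcript length and GC content was removed from each library, it was -0.071 (95% interval -0.15 to 0.013), 60.2% of its value; 99.3% of the members have a length and GC value. With the oligodendrocyte covariate it was -0.085 (95% interval -0.24 to 0.067), 72.8% of its value. Both explanations stay open, since each took away part of the difference and left an interval that includes 0. A change with diet stays open too, and the pattern could be technical in part.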

How the results depend on the processing

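Leaving out control replicate 4 with CD replicate 1 (the ends of the first principal component), the choroid plexus covariate, the removal of a length and GC trend, and the exact permutation of list means were chosen after seeing the data. The cause of a change was not tested unless one is given.

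Beyond the counts, 115 values of named genes and lists were recomputed 4046 times. Of these, 3582 kept their direction and their side of the threshold, 424 lost their call, 4 gained one and 36 reversed; 0 of the reversed values were called in the alternative. Apart from the other thresholds, calls kept under every alternative numbered 7 of 21 named genes in CR against control (Hspa1b, Fos, Fosb, Rrad, Fosl2, Hspa1a and Nr4a3), 15 of 21 in CD against control and 0 of 11 in CR against CD, or 12, 15 and 1 (Per1) with the oligodendrocyte covariate set aside.

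Pseudocounts, filters, the scalings, fits of only the groups compared, edgeR, the neighbouring-region covariate and the block by title numbers left all gene counts within 1.5 times. With columns rescaled to the same total, the split in CR against control was 151 higher and 410 lower. Array weights gave 31 genes in CR against CD. DESeq2 called 766 in CR against control, 73 in CR against CD and 317 in both diets. At an adjusted p under 0.10 the counts were 936 in CR, 1114 in CD and 426 in both; under 0.01 they were 131, 141 and 54, and 3 in CR against CD, by construction. Replicate numbers from the descriptions, which differ from the titles for 1 CR library, gave 282 in CR and 129 in both as a block. Libraries of the same title number correlated at -0.17 to 0.27, above 0.1 in 5 of 16 pairs, pairs with a control library included. Pairs of a CR with a CD library ran from -0.071 to 0.10. Such correlations cannot show whether the numbers mark feeding pairs. The numbers were not taken as the feeding pairs of CR and CD mice because the labels do not identify these pairs. Leaving out both libraries gave 19 in CR against CD.

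The oligodendrocyte covariate left 23 genes in CR against control, 0 in CR against CD (limma, 1083 at an unadjusted p under 0.05) and 21 in both. The marker score itself, here without the mean of all genes taken off as in the list tests, differed between CR and control by -0.26 (exact permutation p = 0.0108) and between CR and CD by -0.20 (exact permutation p = 0.00433), so this covariate takes part of the diet contrast and widens standard errors. Under it Cartpt (0.26), Hcrt (-0.0056) and Ghsr (-0.15) reversed in CR against control, as did the respiratory chain (0.011) and striatum (-0.11) lists. The oligodendrocyte list, whose mean is the covariate, was brought near 0 by construction (0.038 in CR against control, a change of sign, and -0.027 in CR against CD). Ghsr reversed in CD against control (-0.040). In CR against CD, Npy (-0.27), Pomc (-0.24), Ghsr (-0.11) and Mc4r (-0.037) reversed. Further reversals in CR against CD were Npy with the block by descriptions (-0.000993) and the neighbouring-region covariate (-0.00269), Pomc with array weights (-0.027), Pmch with the trend removed (0.0090) and Ghsr without both libraries (-0.019).

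Lists called with the oligodendrocyte covariate numbered 25 in CR against control and 23 in CR against CD, and 20 in CR against CD without both libraries. The estimated correlation gave 0, 0 and 0 lists, fry 7, 4 and 2, and the exact permutation 0, 0 and 0. For the exact permutation, 1 list alone at the smallest possible p of 0.00216 could not be called.

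Over the 17 fits that left out 1 library, genes called ranged from 202 (CR replicate 6) to 540 in CR against control, from 306 (control replicate 2) to 759 in CD against control, from 1 (CR replicate 3) to 33 (CR replicate 2) in CR against CD, and from 110 (CR replicate 6) to 241 in both. Lists ranged from 12 to 19, from 9 to 17 (control replicate 1) and from 8 to 16 (CD replicate 1). Core genes near 0 changed sign: Cartpt (-0.19 to 0.11) and Ghsr (-0.15 to 0.18) in CR against control, Ghsr (-0.12 to 0.087) in CD against control, and Npy (-0.057 to 0.13), Pomc (-0.088 to 0.21), Hcrt (-0.21 to 0.0074), Pmch (-0.20 to 0.058) and Ghsr (-0.16 to 0.18) in CR against CD.

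Depth was alike in all libraries. At 0.0581 to 0.0617 CPM per read, Agrp rested on few reads per library, and an error of counting adds to the spread between mice there.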
